A study of Acinetobacter oleivorans DR1 with 2 samples.

How the data were processed

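RNA was sequenced from Acinetobacter oleivorans DR1, a soil bacterium that grows on alkanes, after exposure to hydrogen peroxide. Per the labels, cultures in nutrient broth were grown to an optical density of about 0.4 (another label gives 0.5 to 0.6) and treated for 15 min with 0.1 mM or 1 mM hydrogen peroxide. The labels give 1 library per dose, made from total RNA with a stranded mRNA library kit. No untreated library was analysed here.

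Reads were aligned with Bowtie2, per the submitters' processing notes, which give no version. The genome build, the annotation release, the counting tool and the use of strand in counting are not given in the sources used here. The deposited read counts were whole numbers per gene for 3911 genes. The deposited RPKM values are named RPKM by the authors, for reads per kilobase relative to library size; a summary sheet calls the same values FPKM, per the file headers. The length they imply is shorter than that of the gene, in proportion most so for short genes. The remaining deposited signal values were counts multiplied by the authors with 1 RLE or 1 TMM factor per library, per the file headers. The authors' TMM factors, which multiply counts directly, had a ratio of 0.796, smaller over larger. The library totals used here, each multiplied by its own TMM factor, also had a ratio of 0.796, smaller over larger. Both ratios include library size, unlike the ratio of the TMM factors given below. No other sample had a column in these tables. The name of the 1 mM column carries a suffix, B, that no label explains, and the column was matched to its library by dose.

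The table held 89 ribosomal and transfer RNA genes, all with a count of 0 in both libraries, and 1 gene for RNase P RNA. These 90 genes were left out of the main analysis, which used 3821 protein-coding genes and pseudogenes. Genes were selected as RNA by product name or by their class in the reference table named below. A first pattern for the product names also took out 4 protein genes and was corrected after the values had been seen. Product names came from the deposited table. Symbols came from the deposited table where it named a gene by symbol, and otherwise from the reference table by locus tag. In all, 978 genes had a symbol. Product names were not used for 289 genes, which were identified by symbol or locus tag alone. For some genes the symbol and the product name disagree (phoB, pstA and nfuA among them), and the symbol is used here. By locus tag, 3710 genes matched the reference table of assembly ASM19679v1. Positions are those of the deposited table, on contig 1, whose build is not named.

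Counts were scaled with TMM factors (0.963 at 0.1 mM, 1.04 at 1 mM) from edgeR 4.0.16 in R 4.3.3. The log2 ratio of 1 mM over 0.1 mM was computed with a prior count of 0.5. Its 95% interval is the conditional exact binomial (Clopper-Pearson) interval. A gene was measured if its larger count was at least 50. A measured gene was counted as higher or lower if the ratio was at least 2-fold and the interval excluded a ratio of 1. This rule is not a test: with 1 library per dose no spread between cultures could be estimated, and no p-value is given. Intervals cover counting error only, since reads are not independent molecules.

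The 28 gene lists, the 2-fold rule, the named-genes rule and all alternatives but 3 were fixed before the data were examined. List members were matched by symbol or by words in the product name, and 17 members were then removed by name, before their values were seen, because a word had matched the wrong gene. For each list with at least 3 measured members, the median log2 ratio was ranked among 10000 random lists of the same size matched on deciles of mean expression. These ranks describe the 2 libraries. Random lists took genes singly, so they do not allow for list members that lie in the same run of neighbouring genes. A rank is therefore no measure of chance. The genes named in the text were, among those past the 2-fold rule, the 12 with the largest and the 12 with the smallest ratios. To these were added up to 3 measured members of each such list with the largest ratios in size, whether or not past the rule, the 5 most abundant genes of each library, and the genes for catalases, AhpC, AhpF, OxyR, RecA, Dps or bacterioferritin, Fur and superoxide dismutase. Genes of hypothetical product were named by locus tag only where they were among the 12. Other named members of a list were chosen after their values were seen. Shares of counts have exact Clopper-Pearson 95% intervals.

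Alternatives were RLE factors, upper-quartile factors, total counts only, the deposited RPKM (log2 of the value + 1), the deposited RLE and TMM values, a prior count of 5, other minimum counts and thresholds, RNA genes kept, the deeper library thinned, unmatched random lists and removal of a trend on gene length (lowess, statsmodels 0.14.6). Remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 2-fold rule was tested on simulated data for 1 mM against 0.1 mM over 3821 genes. It recovered 50 of 50 genes in each of 4 sets, changed 3-fold or 6-fold in either direction, and called 0 of 3621 unchanged genes. The simulated counts held counting error only, and the changed genes were drawn only from genes with expected counts above the minimum of 50. Changes near 2-fold were not simulated, so the test does not cover genes near the threshold. Slopes along runs of at least 4 same-strand genes, at most 50 bases apart, were set against 1000 shuffles of gene order, with intervals from 2000 bootstrap draws.

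The libraries held 28514177 counts at 0.1 mM and 32522551 at 1 mM, of which 27300896 and 31821185 lay in the genes analysed. At this depth the median gene had a log2 interval of 0.14 on either side. A count of 0 allowed up to 0.114 and 0.0908 CPM (scaled counts relative to library size), equal to 3 counts.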

Results

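Transcript levels of A. oleivorans DR1 were compared between a culture treated with 1 mM hydrogen peroxide and a culture treated with 0.1 mM, each for 15 min. The design asks how hydrogen peroxide acts on this bacterium, and the 2 libraries allow a comparison of dose. Each dose had 1 library, with 28514177 counts at 0.1 mM and 32522551 at 1 mM. Of 3821 genes, 3604 were measured.

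At 1 mM, the catalase-peroxidase gene katG, the alkyl hydroperoxide reductase gene ahpC and the iron storage genes ftn and bfr were more than 2-fold higher than at 0.1 mM. The lists for iron-sulfur cluster assembly, DNA repair and sulfur assimilation had median ratios above nearly all random lists. Those for NADH dehydrogenase, ATP synthase, terminal oxidases, ribosomal proteins and aromatic catabolism had medians below all of them. In all, 434 of the 3604 genes were at least 2-fold higher, 510 were at least 2-fold lower and 2660 were neither. The split depended on scaling: with total counts only, 538 genes were higher and 436 were lower. With the deposited RPKM, where 1 was also added to each value, 525 genes were higher and 361 were lower. The median log2 ratio of all measured genes was 0.03 here, 0.15 with the deposited RPKM and 0.13 with total counts only, so ratios are to be read relative to these centres. No difference has a replicate check, and dose cannot be separated from any other difference between the 2 cultures or libraries.

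In the peroxide detoxification list, which holds enzyme genes and the regulator gene oxyR, 3 of 14 measured genes were higher at 1 mM, 1 was lower and 10 were neither. The largest ratio belonged to AOLE_RS16400 (positions 3486388 to 3486819), a peroxiredoxin of the Ohr family, whose members reduce organic hydroperoxides. It was 9.54-fold higher (log2 ratio 3.25, interval 3.20 to 3.30). The catalase-peroxidase gene katG (positions 3700222 to 3702378) was 4.09-fold higher (log2 2.03, interval 2.03 to 2.04). The peroxidase subunit gene ahpC (positions 2852427 to 2852990) was 2.68-fold higher (log2 1.42, interval 1.42 to 1.42). Both genes named ahpF, for the reductase subunit that recharges AhpC, stayed under 2-fold, with log2 ratios of 0.79 (AOLE_RS11430) and 0.74 (AOLE_RS13420). Whether the 2 genes share reads is not known. The catalase gene katE had a log2 ratio of 0.69. Of the other catalase genes, AOLE_RS12765 was 2.67-fold lower (log2 -1.42, interval -1.68 to -1.16), while the interval of AOLE_RS09860 spanned 0 (log2 -0.06, interval -0.26 to 0.13). The interval of oxyR, the gene for the peroxide-sensing regulator, also spanned 0 (log2 -0.01, interval -0.05 to 0.03), and neither is given a direction. The list as a whole had a median of 0.34, above 8921 of 10000 random lists and within their central 95%.

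**Figure D1:**
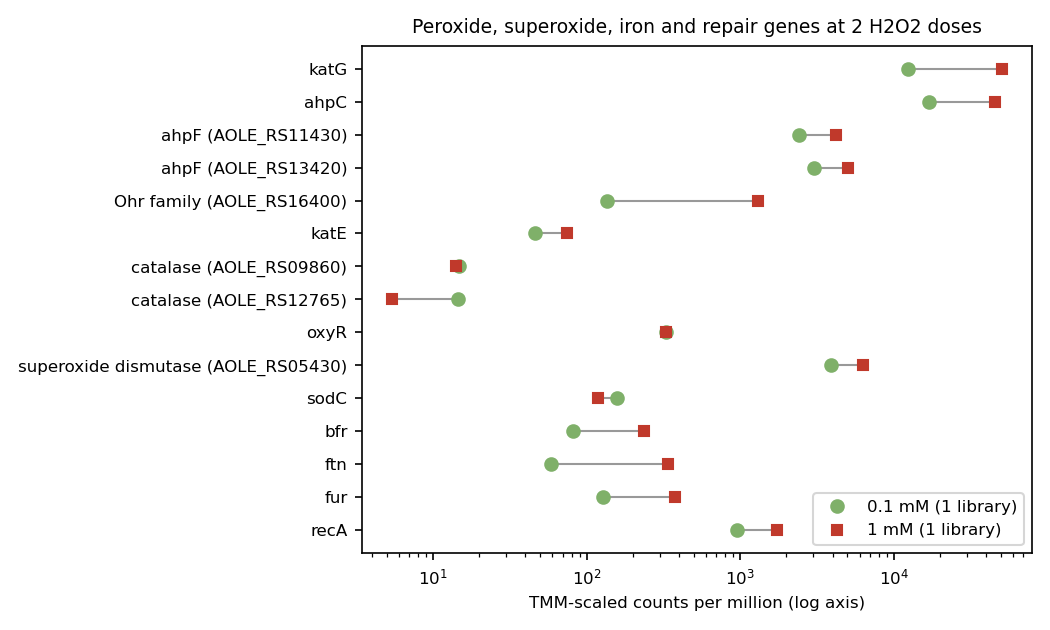
TMM-scaled CPM (log axis) of 15 peroxide, superoxide, iron and repair genes at 0.1 mM (circles) and 1 mM (squares) hydrogen peroxide, 1 library per dose. Both katG and ahpC were already abundant at 0.1 mM and were 4.09-fold and 2.68-fold higher at 1 mM, while the oxyR points overlap.

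The superoxide dismutase gene AOLE_RS05430 had a log2 ratio of 0.68 and sodC, for the copper-zinc enzyme, -0.42. Within the list of superoxide and nitric oxide genes, 0 of 4 were higher and 1 was lower, the flavohemoprotein gene AOLE_RS02095 at -1.99. The median of -0.17 exceeded 3958 of 10000 random lists. Thiol redox genes gave 2 higher, 2 lower and 20 neither of 24, with a median of 0.04 that exceeded 5174 random lists. The higher pair were trxA, for thioredoxin (log2 1.13), and the glutathione S-transferase gene AOLE_RS17425 (1.10). The lower pair were another glutathione S-transferase gene, AOLE_RS06875 (-1.31, under 2-fold with the deposited RPKM), and AOLE_RS04735 (-1.33), for a glutathione-dependent formaldehyde-activating enzyme.

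Both measured iron storage genes were higher, ftn at log2 2.53 (5.77-fold, positions 3329311 to 3329775) and bfr at 1.54 (2.91-fold, positions 348940 to 349404). The gene for the iron-responsive repressor Fur was 2.92-fold higher (log2 1.55, interval 1.49 to 1.60). Of 8 iron-sulfur cluster assembly genes, 4 were higher and 0 were lower, with a median of 0.93 above 9949 of 10000 random lists. These were nfuA (2.30), erpA (2.22), iscU (1.27) and iscA (1.11), which code for carriers and scaffolds of the clusters. Iron acquisition moved both ways, with 9 of 42 genes higher, 4 lower and 29 neither. Its median was -0.19 and its mean 0.12, so these differ in sign, and the median exceeded 1097 random lists. The largest ratios in that list were those of the siderophore synthesis genes AOLE_RS07235 (3.29) and entE (2.69) and of the heme oxygenase gene AOLE_RS14750 (2.30). The lower members were the TonB-dependent receptor gene AOLE_RS18560 (-1.45), the ExbB gene AOLE_RS17175 (-1.39), the ferrous iron transporter gene AOLE_RS09825 (-1.14) and the ExbD gene AOLE_RS09645 (-1.09). AOLE_RS09825 and AOLE_RS09645 fell short of 2-fold with the deposited RPKM, and AOLE_RS09645 also with total counts.

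DNA repair genes were higher as a group. Of 36 genes, 6 were at least 2-fold higher and 0 were lower, and 32 had a ratio above 0. The median of 0.59 exceeded 9994 of 10000 random lists. The repair glycosylase gene mutM, whose product removes oxidised guanine, was 3.75-fold higher (log2 1.91, interval 1.80 to 2.02). Genes annotated as subunits of DNA polymerase V, a translesion polymerase, had log2 ratios of 1.75 (AOLE_RS14855) and 1.64 (AOLE_RS11780). The recombinase gene recA was 1.81-fold higher (log2 0.86, interval 0.84 to 0.88), under the 2-fold rule. Of 16 heat shock and protease genes, 5 were higher and 0 were lower. These were lon (1.42), groEL (1.38), grpE (1.32), htpG (1.30) and dnaK (1.25), for a protease and chaperones. The list median of 0.39 exceeded 9686 random lists, inside the central 95%. None of 4 sigma factor genes passed the rule (median -0.13, above 4357 random lists). The heat shock sigma factor gene rpoH had a log2 ratio of 0.48, and the sigma factor genes AOLE_RS04455 and AOLE_RS12535 had -0.31 and -0.47.

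Sulfur assimilation and cysteine synthesis had 13 of 40 genes higher, 2 lower and 25 neither. The median of 0.63 exceeded 10000 of 10000 random lists. The largest ratios were those of tauD (log2 2.58), ssuD (1.99) and ssuC (1.72), which serve the uptake and use of taurine and alkanesulfonates as sulfur sources. The lower pair were the sulfate ester-binding protein gene AOLE_RS09630 (-1.29) and the alkanesulfonate monooxygenase gene AOLE_RS09750 (-1.03). Both fell short of 2-fold with the deposited RPKM, and AOLE_RS09750 also with total counts, upper-quartile factors or a prior count of 5. Amino acid synthesis operons for histidine, leucine, isoleucine, valine, arginine and tryptophan divided into 7 higher, 3 lower and 20 neither, with a median of 0.21 above 8283 random lists. Examples were hisB (1.37) and argC (1.37), both higher, and argF (-1.55), trpB (AOLE_RS10345, -1.37) and argD (start 393362, -1.35), all lower. The other genes of these names were neither, with 0.51 for trpB (AOLE_RS02960) and 0.01 for argD (start 2966652). The lower argD lies near the arginine breakdown gene astA (AOLE_RS01845, start 394595), which was lower too (-2.15).

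Respiratory chain and ATP synthase transcripts were lower at 1 mM. All 11 matched genes of NADH dehydrogenase I, the proton-pumping entry point of electrons, had ratios below 0, and 8 of them were at least 2-fold lower. No gene named nuoA or nuoB was matched. The median of the 11 genes, -2.21, lay below 10000 of 10000 random lists. These genes form 1 run, whereas the random lists took genes singly. The lowest values were those of nuoM (5.89-fold lower, log2 -2.56, interval -2.58 to -2.53, positions 3374207 to 3375805), nuoN (-2.54) and nuoL (-2.52). Of 9 ATP synthase genes, 8 were lower, with a median of -1.65, also below all 10000 random lists. Among them were AOLE_RS18620 (-1.98), atpG (-1.91) and atpD (-1.91). The gene that was not lower, AOLE_RS18660 for subunit I, had 0.11. The list of terminal oxidases and cytochrome bc1, in which no bc1 gene was matched, gave 7 lower and 5 neither of 12, with a median of -1.37 below all 10000 random lists. The cytochrome bd oxidase genes AOLE_RS08310 and cydB (AOLE_RS08305), at positions 1756694 to 1758280 and 1755552 to 1756697, were 23.5-fold and 22.8-fold lower. Other cytochrome d oxidase subunit I genes and cydB genes of the list stayed under 2-fold. They were AOLE_RS07805 (-0.62), cydB (AOLE_RS07800, -0.77), AOLE_RS11540 (-0.96) and cydB (AOLE_RS11545, -0.82). The cytochrome o oxidase gene AOLE_RS06455 had a log2 ratio of -1.75. Along the 11 nuo genes the ratio descended in the order of transcription from -0.33 at nuoC to -2.56 at nuoM, and nuoN, the last, had -2.54. A fall of this kind was widespread: over 103 runs of at least 4 same-strand genes the median slope was -0.15 per gene, and 77 slopes were negative. Many ribosomal protein genes and 10 genes of the paa run also lie in such runs.

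Ribosomal protein genes were also lower, with 0 of 42 higher, 19 lower and 23 neither. Their median of -0.91 lay below all 10000 random lists. The lowest were rplP (-1.85), rpmC (-1.82) and rpsQ (-1.73), neighbours at positions 457966 to 458830. Translation factor and aminoacyl-tRNA synthetase genes had 2 of 33 higher and 0 lower, with a median of 0.37 above 9913 random lists. Ratios were above 0 for 25 of them and below 0 for 8, among these the factor genes infB (-0.59), fusA (-0.54) and tsf (-0.48). The higher pair were trpS (1.23) and prfC (1.01), and lysS lay at the threshold (1.00). The elongation factor gene tuf (start 3270521) had a log2 ratio of -0.82, and its near-identical second copy (start 3844645) had -0.98. Each value is uncertain because the copies can share reads, though both lay below 0.

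In the list of phenylacetate, benzoate and other aromatic catabolism, 19 of 39 genes were lower, 1 was higher and 19 were neither. The median of -0.99 lay below all 10000 random lists. The phenylacetate-CoA ligase gene paaK (positions 2757879 to 2759168) was 27.4-fold lower (log2 -4.78, interval -4.91 to -4.65), and AOLE_RS12880 and paaG had -4.39 and -4.27. The 1 higher member, AOLE_RS09955 (2.65), makes a siderophore precursor and had been matched by a word. Without it the median was -1.06. Ratios differed along the 10 genes of the paa run, from -1.28 at the first gene, paaA, to -4.78 at the last, paaK, with 1 step upward, at pcaF. The paaZ gene, at the paaA end of the phenylacetate operon but outside this run, had -2.35, below paaA. Falling ratios were also seen over the 100 runs other than those of nuo, atp and paa genes (median slope -0.14 per gene). In the beta-oxidation list 14 of 37 genes were lower, 2 were higher and 21 were neither, and the median of -0.87 lay below all 10000 random lists. Its lowest members, AOLE_RS12905 (-4.34), paaG and AOLE_RS12915 (-4.03), lie in the phenylacetate operon. Without that operon the median of the remaining 33 genes was -0.75. The genes of the fatty acid oxidation complex, fadB (-0.18) and fadA (-0.24), were neither higher nor lower by the rule. The higher members were acyl-CoA dehydrogenase genes, AOLE_RS01965 (2.17) and AOLE_RS11285 (1.80). Of 4 alkane degradation genes 0 passed the rule, with a median of 0.09 above 5620 random lists. Their ratios included 0.45 for the alkane monooxygenase gene AOLE_RS13400, 0.34 for rubB and -0.18 for rubA.

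**Figure D2:**
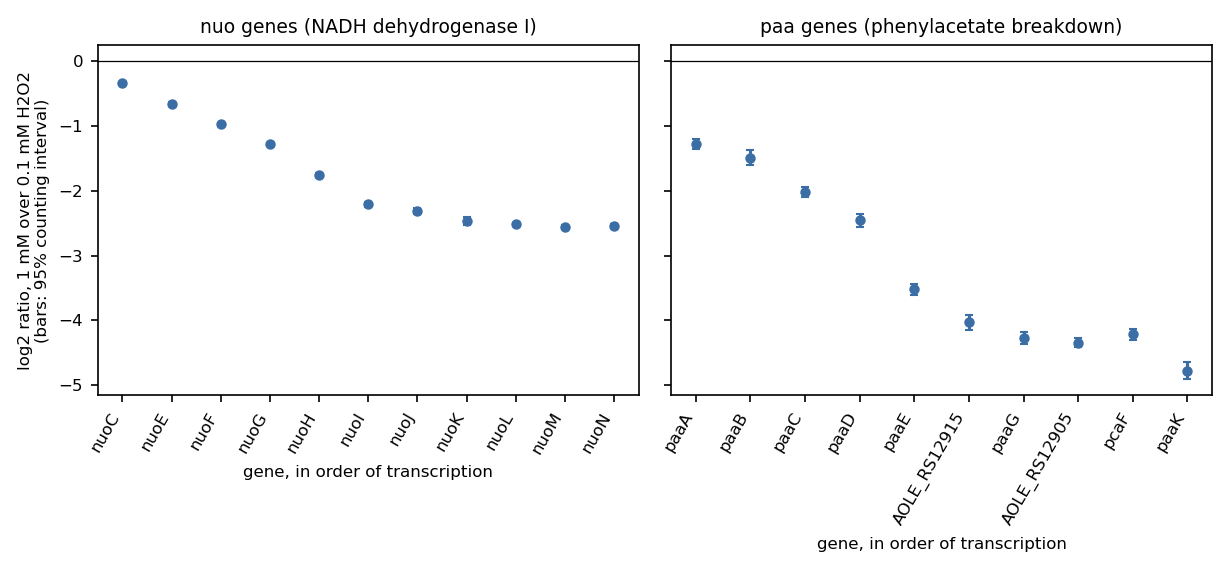
Log2 ratio (1 mM over 0.1 mM hydrogen peroxide, vertical axis) of the nuo genes and the paa genes in order of transcription (horizontal axis), with 95% counting intervals as bars, 1 library per dose. The ratio is -0.33 at nuoC and -2.54 at nuoN, and -1.28 at paaA and -4.78 at paaK, with small upward steps at nuoN and pcaF. The paaZ gene (-2.35) lies outside the run of paa genes and is not shown.

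Central carbon metabolism gave a mixed picture. In the TCA cycle and glyoxylate shunt 2 of 21 genes were higher, 1 was lower and 18 were neither, with a median of -0.39 above 731 random lists. The isocitrate lyase gene AOLE_RS14285, for the entry enzyme of the glyoxylate shunt, was 2.49-fold higher (log2 1.32, interval 1.31 to 1.32). The malate synthase gene AOLE_RS10780 had -0.01, with an interval that spanned 0. A gene annotated as malate dehydrogenase, AOLE_RS18695, had a log2 ratio of 2.04. Another gene with that annotation and more counts, AOLE_RS02410, had -0.11. The isocitrate dehydrogenase gene icd had -1.01, which fell short of 2-fold with total counts, upper-quartile factors or the deposited RPKM. It had 937 counts at 0.1 mM and 584 at 1 mM. The far more abundant isocitrate dehydrogenase gene AOLE_RS04880 (74196 and 143715 counts) had 0.62. Pentose phosphate, NADPH supply and gluconeogenesis had 1 of 15 genes higher and 5 lower, with a median of -0.53 above 430 random lists. The lower members were the 3 NAD(P) transhydrogenase genes AOLE_RS16650 (-1.86), AOLE_RS16645 (-1.84) and AOLE_RS16640 (-1.75), pgi (-1.56) and eda (-1.01). Like icd, eda fell short of 2-fold with total counts, upper-quartile factors or the deposited RPKM. The higher member was sthA (1.13), for a soluble transhydrogenase.

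Among surface, export and mobile functions, multidrug efflux and type VI secretion were low. Of 50 multidrug efflux genes 8 were lower, 2 were higher and 40 were neither, and the median of -0.44 lay below 9978 of 10000 random lists. Members included adeC (-2.07) and adeT1 (-1.54, under 2-fold with the deposited RPKM), with AOLE_RS09380 (2.30) and AOLE_RS01395 (1.38) higher. Type VI secretion, a contact-dependent injection system, had 6 of 16 genes lower and 0 higher, with a median of -0.56 below 9794 random lists. Its lowest members were tagF (-1.90), tssM (-1.55) and tssK (-1.40). The genes tagF and tssM are minus-strand neighbours, and whether the trend along gene runs lowers members of this list was not tested. Exopolysaccharide and biofilm genes gave 3 lower and 4 neither of 7, with a median of -0.70 above 356 random lists. These were pgaC (AOLE_RS06500, -1.32), pgaB (AOLE_RS06495, -1.19) and pgaD (AOLE_RS06505, -1.15), of which pgaB and pgaD were under 2-fold with the deposited RPKM. The second copies of these genes were neither, with 0.42 for pgaC (AOLE_RS14640), 0.87 for pgaB (AOLE_RS14645) and -0.11 for pgaD (AOLE_RS14635). Type IV pili had 2 of 16 genes higher, pilB (1.25) and tfpZ (1.08), and 1 lower, AOLE_RS10885 (-1.02), with a median of 0.13 above 6134 random lists. Metal efflux had 1 of 8 genes lower, AOLE_RS16210 for a copper resistance protein (-1.03), with a median of -0.10 above 2910 random lists. AOLE_RS10885 and AOLE_RS16210 fell short of 2-fold with total counts, upper-quartile factors or the deposited RPKM. The 3 prophage and mobile element genes were 1 higher (AOLE_RS15125, 1.15), 1 lower (AOLE_RS13240, -1.24) and 1 neither (AOLE_RS07515, 0.70), with a median of 0.70 above 8509 random lists. The 1 measured toxin-antitoxin gene had a log2 ratio of 0.10.

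**Figure D3:**
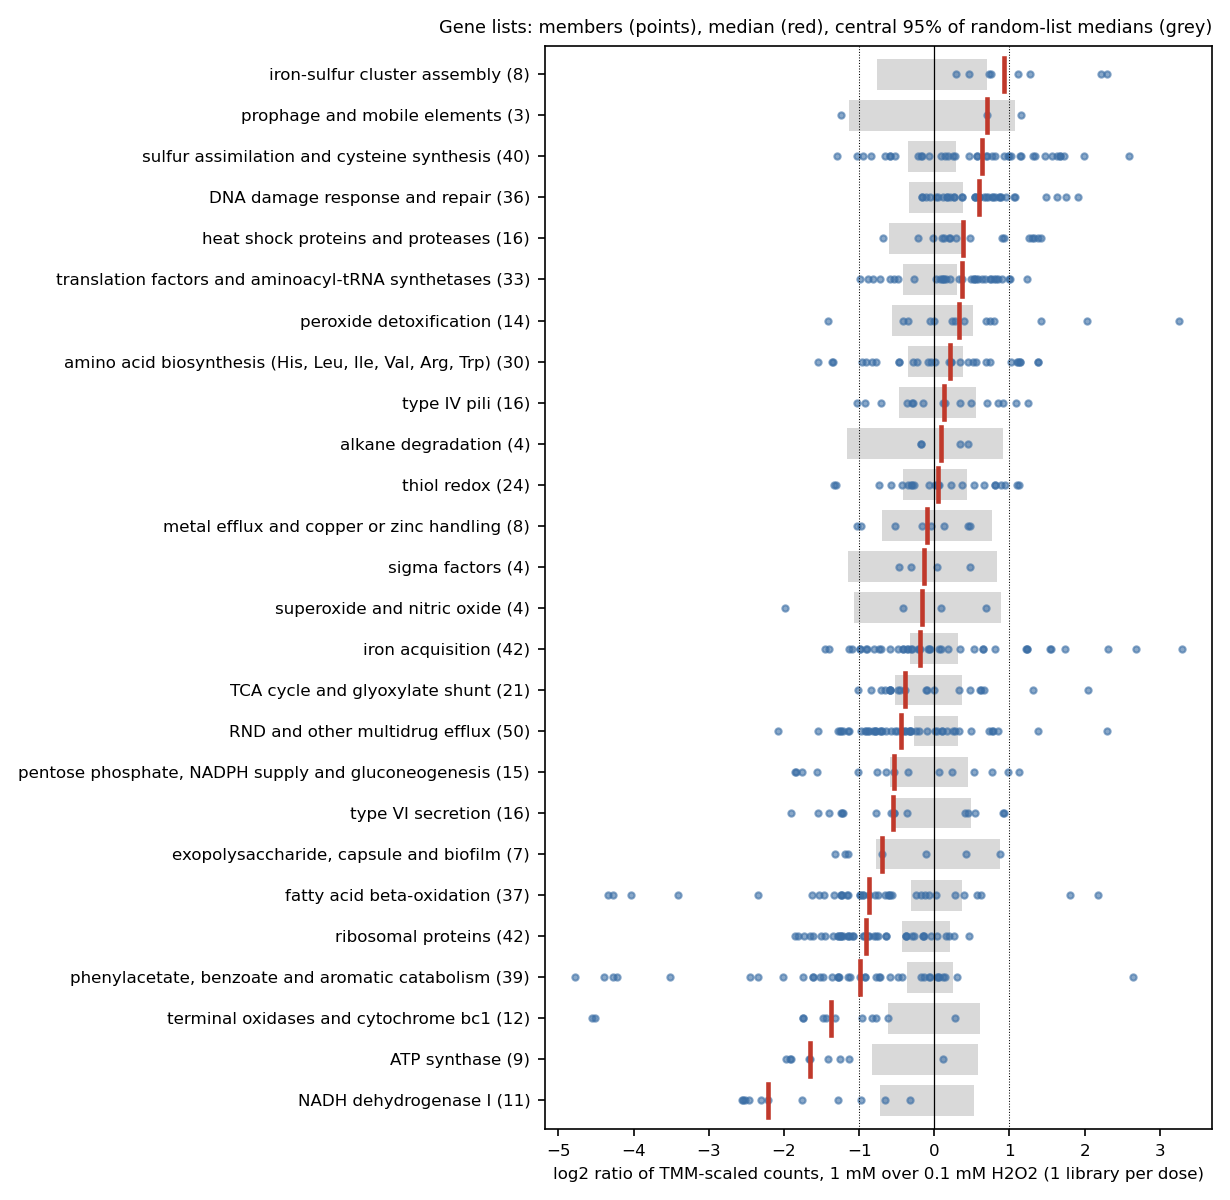
Log2 ratio (1 mM over 0.1 mM hydrogen peroxide, horizontal axis) of the members (points) of 26 gene lists, with the list median (red) and the central 95% of the medians of 10000 random lists (grey); dotted lines mark a 2-fold ratio and numbers in brackets are measured genes. The lowest median is that of NADH dehydrogenase I (-2.21) and the highest that of iron-sulfur cluster assembly (0.93).

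Of the 26 lists with at least 3 measured members, 4 lay above the central 95% of their random lists and 8 below it. Lists whose members share a run of neighbouring genes were ranked as if those genes were independent. The single genes with the largest ratios included several for phosphate uptake. AOLE_RS05030 (positions 1078863 to 1079894), annotated as a substrate-binding protein for phosphonate transport, was 22.8-fold higher (log2 4.51, interval 4.43 to 4.59). Its neighbours pstC (3.25) and pstA (2.94), the regulator gene phoB (3.21) and the alkaline phosphatase gene AOLE_RS17120 (3.41) were also among the 12 largest. The others were AOLE_RS08285, of unknown function (4.10), the porin gene AOLE_RS10445 (3.67), ribB of riboflavin synthesis (3.44), the dicarboxylate transporter gene AOLE_RS19340 (3.43) and the acetyltransferase gene AOLE_RS15240 (3.01), with AOLE_RS07235 and AOLE_RS16400 above. The smallest ratio was that of AOLE_RS17990 (positions 3827222 to 3827806), a gene of unknown function that was 55.8-fold lower (log2 -5.80, interval -5.90 to -5.70). Others among the 12 smallest were AOLE_RS08300 (-4.87) and AOLE_RS08295 (-4.24) beside the cytochrome bd genes, pcaF (AOLE_RS12900, -4.22), AOLE_RS09845 (-4.15) and the methylcrotonyl-CoA carboxylase gene AOLE_RS11890 (-4.10).

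The genes with the most counts also differed between the libraries. Abundance here means share of counts, which were not divided by gene length, so long genes rank higher than by number of transcripts. For example, katG spans 2157 bases and ahpC 564, so their order by counts need not be their order by transcript number. The 5 most abundant genes held 10.2% of coding counts at 0.1 mM (interval 10.2 to 10.2) and 16.8% at 1 mM (interval 16.8 to 16.8). At 0.1 mM these were omp38, for an outer membrane protein (2.93%), tuf (start 3270521, 2.05%), fusA, for an elongation factor (1.95%), ahpC (1.64%) and rpsA, for a ribosomal protein (1.61%). At 1 mM they were katG (5.24%, from 1.19% at 0.1 mM), ahpC (4.74%), AOLE_RS14285 (3.16%, from 1.17%), omp38 (2.21%) and fusA (1.45%). The log2 ratios of omp38, fusA and rpsA were -0.52, -0.54 and -1.26.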

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

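No test in this part was chosen after its result was seen. The RNase P RNA gene AOLE_RS19555 (positions 3292742 to 3293097, minus strand), whose product is the catalytic RNA that trims transfer RNA precursors, stood outside the protein-coding comparison and held a large number of reads. It had 1213281 counts at 0.1 mM and 701366 at 1 mM, far above the 3 counts that a count of 0 allows. These were 4.26% (interval 4.25 to 4.26) and 2.16% (interval 2.15 to 2.16) of all counts, and with the coding-gene factors the ratio was 2.17-fold lower at 1 mM (log2 -1.12, interval -1.12 to -1.12). All 89 ribosomal and transfer RNA genes had a count of 0 in both libraries.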

How the results depend on the processing

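The symbol match for ribosomal proteins, the aromatic list without the siderophore gene and the beta-oxidation list without the phenylacetate operon were chosen only after the results were seen. No paired analysis was possible because each dose had 1 library. The median ratios of the 26 lists kept their place inside or outside the central 95% of random lists under all alternatives run (263 values). Settings that change only the scaling factors (RLE, TMM, upper-quartile, total counts) move all ratios nearly alike. Those values could therefore hardly change a rank. Lists with medians near 0 that lay inside it, metal efflux and sigma factors, changed sign with the deposited RPKM, and metal efflux also with total counts only. Ribosomal proteins matched also by symbol gave a median of -0.89 over 55 genes. The count of genes followed the threshold by construction: at 1.5-fold 905 genes were higher and 903 lower, and at 4-fold 54 and 92. With RNase P RNA in the total, the share of the 5 most abundant coding genes at 0.1 mM was 9.75% and the share of the 5 most abundant coding genes at 1 mM was 16.4%, since the total grew. Every other count of higher or lower genes stayed within 1.5 times the main count. The gene numbers that were higher and lower were 538 and 436 with total counts only, 498 and 464 with upper-quartile factors, and 427 and 513 with the deeper library thinned. All 436 genes lower with total counts and all 361 lower with the deposited RPKM were among the 510. For total counts this follows from the nearly uniform upward shift of the ratios. Of the values of named genes under other settings, 733 stayed on their side of the 2-fold rule, 13 fell short of it, 3 passed it newly (lysS) and 0 changed direction past it. Those short of it were icd, AOLE_RS10885 and AOLE_RS16210 under 3 scalings and pgaB, pgaD, AOLE_RS06875 and adeT1 with the deposited RPKM. Of genes named after their values were seen, 248 values stayed and 11 fell short (AOLE_RS09630, AOLE_RS09645, AOLE_RS09750, AOLE_RS09825 and eda). A check of GC content was not run, because no genome sequence was used here. Depth limits the gene-level ratios little (smallest count among genes past the rule 12), whereas the missing replicate limits them all.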

Other observations

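The gene groups in the first paragraphs, the test of abundant transcripts and the test by strand were chosen only after the results were seen. Because these groups were picked for their ratios, their counts are descriptions and no independent evidence. Phosphate uptake and its regulation stood out, with 8 of 8 genes higher at 1 mM and a median log2 ratio of 3.07. They include phoR (2.19) and phoU (2.01) beside phoB, pstC, pstA and pstB (2.32). The genes of 2 siderophore clusters were higher while many other iron uptake genes were not. An enterobactin-type cluster (positions 2133763 to 2147243) had 7 of 7 genes higher, with a median of 2.18, and a second cluster (positions 1544316 to 1553566) had 6 of 6 higher, with a median of 2.31. Pyrimidine synthesis had 3 of 7 genes higher, carA (2.11), carB (1.35) and pyrF (1.20).

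A cluster for breakdown of branched-chain acids (positions 2538791 to 2545304) had 5 of 5 genes lower, with a median of -3.41. In the arginine succinyltransferase pathway, which breaks down arginine, 4 of 5 genes were lower, with a median of -2.15, and the second astA gene (AOLE_RS13880) had -0.15. Urease genes moved both ways, from ureA (1.55) and ureC (1.07) through ureE (0.10) to ureG (-1.22), in that order along the minus strand. By the functional categories in the table, energy production (C) had a median of -0.46 and lipid metabolism (I) -0.37, both below 10000 of 10000 random lists. Transcription (K, 0.44), replication and repair (L, 0.52) and coenzyme metabolism (H, 0.51) lay above all 10000.

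Genes late in a run of same-strand neighbours at most 50 bases apart had lower ratios than genes early in it. Over 103 runs of at least 4 genes the median slope was -0.15 per gene (bootstrap interval -0.19 to -0.10), and 77 runs had a negative slope. Chance in the runs first seen (nuo, atp, pst and paa genes, of which pst forms no run of this length) is argued against by the other 100 runs (-0.14, against -0.03 to 0.03 for shuffled order). In 34 runs with a mean ratio near 0 the slope was -0.19 (shuffled order -0.05 to 0.05), so the trend was not confined to runs shifted as a whole. A mean near 0 can also arise from higher early genes and lower late genes, so these runs cannot exclude regulation within operons. A length trend is argued against by the slope after its removal (-0.16), and a trend in chromosome coordinates by the step between close neighbours, which was -0.17 on the plus strand and 0.15 on the minus strand. Whether the trend also crosses gaps of at least 200 bases stayed open (median step -0.063, interval -0.26 to 0.10); slower or broken transcription at 1 mM may account for it, as may RNA loss or library preparation, and none of these was tested because coverage within genes was not analysed here.

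Ribosomal protein, ATP synthase and NADH dehydrogenase transcripts were lower at 1 mM, and a few abundant transcripts could produce such a drop by taking more of the counts. That is argued against by the share of counts outside 7 genes, those among the 5 most abundant of either library. This share went from 87.5% at 0.1 mM to 81.2% at 1 mM, a log2 ratio of -0.11 for all other genes. With total counts only the list medians were -0.80, -1.54 and -2.10 (bootstrap upper bounds -0.54, -1.02 and -0.86). Of the 7 genes, omp38, tuf (start 3270521), fusA and rpsA had smaller shares at 1 mM, which offsets part of the gain of the others. The trend along gene runs could lower late genes of these operons, and the first genes of the 16 runs of at least 2 genes that hold them had a median of -0.82 (bootstrap interval -1.25 to -0.26), too wide to exclude that trend as the only cause. By list the first genes differed. The median was -0.78 for 13 ribosomal runs, and the values were -1.25 (atpE) and -1.91 (atpG) for ATP synthase and -0.33 (nuoC) for NADH dehydrogenase. Runs defined by gaps may start inside longer operons. Next to atpE, atpB (-1.13) and the subunit I gene AOLE_RS18660 (0.11) lay outside these runs, so atpE need not start its operon. A response to dose stays open, since dose and any difference between the cultures are confounded with 1 library each.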
